A study of Mus musculus with 30 samples.

How the data were processed

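Osteoclasts of WT and Terc-/- mice on the C57BL/6J background were profiled by RNA-seq. Terc is the RNA template of telomerase, the enzyme that maintains chromosome ends. Per the labels' protocols, bone marrow-derived macrophages were placed on bone slices with 25 ng/ml M-CSF and 100 ng/ml RANKL, the cytokines that drive osteoclast formation, and were harvested after 2 days or once large multinucleated cells had formed. Libraries were made from polyadenylated RNA with oligo-dT beads and sequenced on an Illumina NovaSeq instrument, per the labels' protocols. Ages were 1, 6 and 20 months, the last for WT mice only.

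The values were deposited as TPM for 45706 Ensembl gene IDs in 5 tables, and the values of each library had the same sum, so the authors had scaled each library to its own total. HTSeq is the tool and mm10 the genome build listed in the submitters' processing notes; versions, the annotation release and the formula are not given in the sources used here. The annotation used here to name genes was GENCODE M21, which is on GRCm38, the assembly called mm10, and gave symbols to 45143 of the IDs. TPM holds no read totals. The number of reads per library is therefore unknown, and no counting interval is given. Low values of a gene stepped in near-whole multiples between libraries: 46.4 to 70.4% of ratios of low genes were whole within 0.02 on the log2 scale, against 1.2 to 2.6% by chance, and from these steps the libraries' depth was 0.683 to 1.524 times that of the first library.

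The tests planned before the data were examined assumed counts, with a fallback for a normalised unit. Since the unit was TPM, the fallback was used: limma 3.58.1 (with statmod 1.5.0, in R 4.3.3) on log2(TPM + 1), with a trend in the prior variance and robust empirical Bayes. Fold changes are therefore on the log2(TPM + 1) scale, which understates the change of genes with low values. The 14238 genes with at least 1 TPM in at least 3 libraries were tested. All 30 libraries entered 1 fit with 7 groups and an additive term for each of the library sets that the titles mark with 519 or gaiwei. The gaiwei term leaves the 1-month WT mean to the libraries without a set mark, while the 519 libraries, shared by both Terc-/- groups, also enter the Terc-/- means. P-values are two-sided and adjusted by Benjamini-Hochberg over genes, and genes under 0.05 are called higher or lower. Interactions were tested as contrasts of the same fit.

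Gene lists were tested with camera (limma) at a preset inter-gene correlation of 0.01, and again with an estimated correlation; 37 of the 40 lists, fixed with the plan, had 3 or more tested genes, and adjusted p-values of lists are over these 37 in each comparison. For each list, members were also adjusted over the list alone. The 2 list symbols Ly6a2 and Lilrb4a were not found in the tables. Values of groups are means and SDs of TPM over the 3 libraries without a set mark.

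The rule for named genes, also part of the plan, took these: Terc and Tert; called genes with a mean of at least 5 TPM in a compared group and no overlap of the libraries without a set mark, up to 8 with the largest change each way, without predicted genes; up to 4 members with the smallest p from lists called by camera or with 3 or more called members, and from the osteoclast, p53 target, cell cycle and senescence lists in any case; and sex-linked genes and Nnt as checks. The rule was written for CPM and applied to TPM. Of the genes it gave, those printed were picked after their values were seen, and some are not reported here. Multi-copy genes (Stfa3, histone, immunoglobulin and MHC genes) can share reads with near-identical copies, and their values are uncertain.

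The fit was tested on simulated data drawn around the means and spreads of the deposited values, with 200 genes changed. Errors were drawn independently for each gene and library, so no simulated library stood apart from its group. A set difference was drawn once per gene and added equally to all libraries with a set mark, so additive set terms held by construction. The real sets were not always additive: Ctsk was at 27.0 TPM in 1-month and 114 in 6-month 519 libraries of Terc-/- cells. In those without a set mark it was at 2690 and 2820. The changed genes had means well above the filter of 1 TPM. The shares below hold for such data and may not hold for the real libraries. In the comparison of Terc-/- and WT at 1 month, 72% of 100 genes changed 2-fold and 100% of those changed 4-fold were recovered, and 8.5% of the calls were false. The shares were 89%, 100% and 6% for 6 against 1 month in Terc-/-, 51%, 94% and 3.3% for the change of the Terc-/- effect with age, and 71%, 99% and 5.6% for 20 against 6 months in WT.

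Alternatives set with the plan were leaving out each library, no filter on low values, no library-set term, only the libraries without a set mark, only the groups compared, a block for the replicate number and the estimated correlation for lists. Added after seeing the data were a pseudocount of 0.1, rescaling each library by its median ratio to the genes' geometric means, a stricter filter at a mean of 5 TPM, TPM recomputed without mitochondrial genes, each library set as its own group, and a comparison within the libraries with a set mark. Tests of other splits of the libraries used every split of 3 against 3, which number 10, or 100 drawn splits. The simulation took its means and spreads from the fit. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3), with genes and lists picked after the values were seen. The raw reads were not used here.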

Results

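Gene expression was compared in 30 libraries of osteoclasts grown on bone slices, in 7 groups set by genotype (WT or Terc-/-), age of the mouse (1, 6 or 20 months) and stage (2 days, or large multinucleated cells). Each group had 3 libraries without a set mark in the title. Both Terc-/- groups had 3 more marked 519, and the 1-month WT group had 3 more marked gaiwei, marks whose meaning is not given in the sources used here. The labels do not say whether replicates came from separate animals, so p-values measure only the spread between these samples. Each gene's spread was estimated from all 30 libraries in 1 fit, so a p-value does not measure the spread of the compared groups alone. Values are mean TPM ± SD of the 3 libraries without a set mark, and fold changes are on the log2(TPM + 1) scale with their SE. Among the genes named in comparisons of 2 groups, the 3 libraries of 1 group lay beyond the 3 of the other, which chance gives for 10% of genes, except where stated. For genes named for the largest change this was a condition of naming, so it adds no support to their p-values.

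Terc (ENSMUSG00000064796, chromosome 3, 96414437 to 96414859, GRCm38), the targeted gene, was at 0 in 27 of the 30 libraries. The other 3 were WT libraries: replicate 4 at 1 month (1.13 TPM), replicate 3 of the multinucleated cells at 20 months (0.516) and replicate 4 of those at 6 months (0.341). WT libraries were thus mostly at 0 as well, so Terc did not check the genotype. Tert, the telomerase protein, reached at most 1.12 TPM.

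Xist (ENSMUSG00000086503, chromosome X, 103460366 to 103483254), which silences an X chromosome in female cells, was at 46.6 to 84.1 TPM in the 3 1-month WT libraries without a set mark and at 0.254 or less in the other 27. Ddx3y, a Y-linked gene, was at 0.0222 or less in these 3 and at 13.6 or more elsewhere. The 1-month WT libraries without a set mark thus read as female and all others, the gaiwei libraries included, as male, so sex and genotype were confounded at 1 month. Eif2s3y, also Y-linked, was at 12.1 to 19.2 TPM in 1-month Terc-/- libraries and at 40.8 to 82.0 in the other libraries with a Y signal. Nnt, a mitochondrial transhydrogenase truncated in the C57BL/6J strain, was at 12.8 to 16.8 TPM in 1-month cells of both genotypes, 10.9 to 11.5 in 6-month Terc-/-, 12.5 to 29.1 in 6-month WT and 27.6 to 28.1 in 20-month multinucleated cells, and 30.9 to 34.5 in 2-day cultures (libraries without a set mark), so low values were not particular to Terc-/-.

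Osteoclast genes were low in all 9 libraries with a set mark. Ctsk (ENSMUSG00000028111, chromosome 3, 95499256 to 95509362), the collagen-degrading protease of osteoclasts, was at 23.5 to 154 TPM in these and at 1500 to 11100 in the other multinucleated cultures. Acp5 (ENSMUSG00000001348, chromosome 9, 22126727 to 22135711), the tartrate-resistant phosphatase that marks osteoclasts, was at 70 to 147 against 1860 to 12100 TPM. Inflammatory genes were high in the libraries with a set mark, with Saa3, an acute-phase protein, at 24100 to 81900 TPM and Il1b at 778 to 6020. The library-set terms held 7187 called genes for 519 (1127 higher, 6060 lower) and 7742 for gaiwei (1227 higher, 6515 lower). The gaiwei term sets male against female libraries by Xist, so sex and library set were confounded in it. These splits depended on scaling: 15.7% of calls were higher in the 519 and 15.8% in the gaiwei libraries as deposited, and 53.2% and 51.3% after median-ratio scaling.

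Of 34 osteoclast genes, 33 were lower in the 519 and 33 in the gaiwei libraries, also when adjusted over the list alone, with medians of -2.19 and -2.24. Camera gave adjusted p = 1.9e-18 and 1.5e-12, but adjusted p = 0.16 and 0.22 with an estimated correlation. Of 27 inflammatory genes, 23 were higher and 1 lower in the 519 libraries (median 1.88, camera adjusted p = 4.9e-30, adjusted p = 0.0016 with an estimated correlation). In the gaiwei libraries 20 were higher and 2 lower, or 21 and 2 adjusted over the list alone (median 2.43, camera adjusted p = 4e-24, adjusted p = 0.0053 with an estimated correlation). Senescence markers split in the gaiwei libraries, 8 higher and 9 lower, with a median of -0.13, a mean of 0.94 and an upward test.

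**Figure D1:**
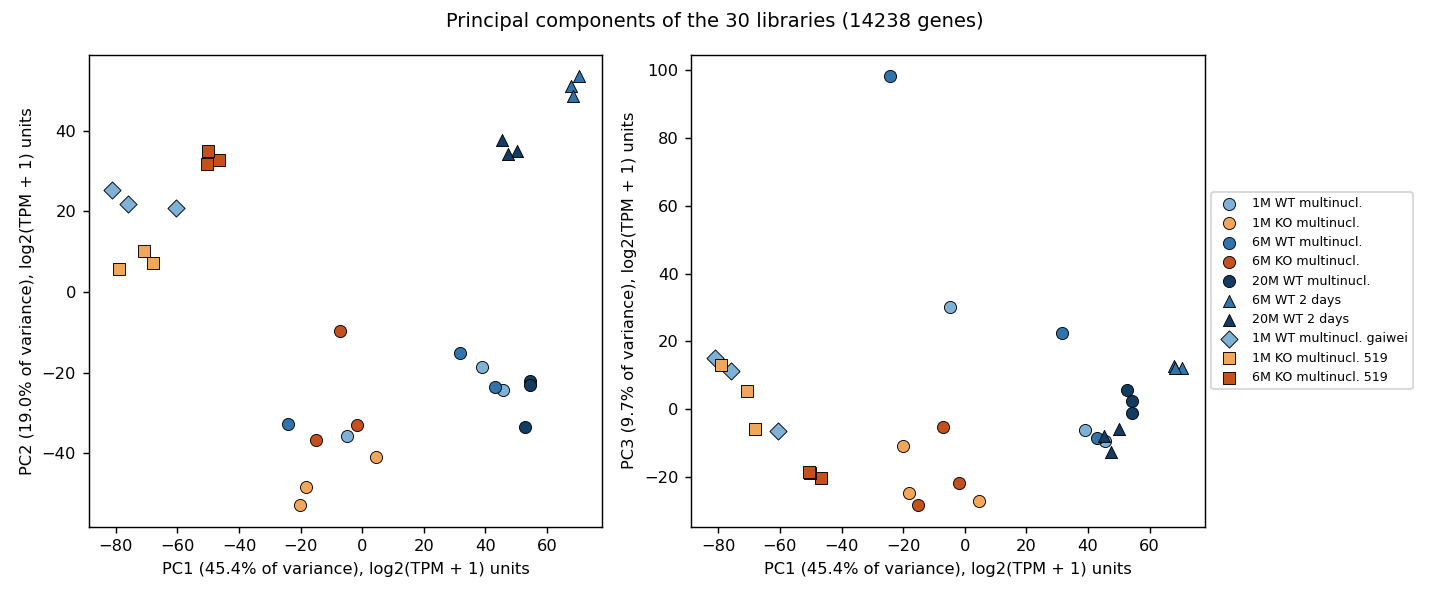
The 30 libraries on the first principal components, which held 45.4% and 19% of the variance. Libraries with a set mark lie at -81.2 to -46.6 on the first.

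**Figure D2:**
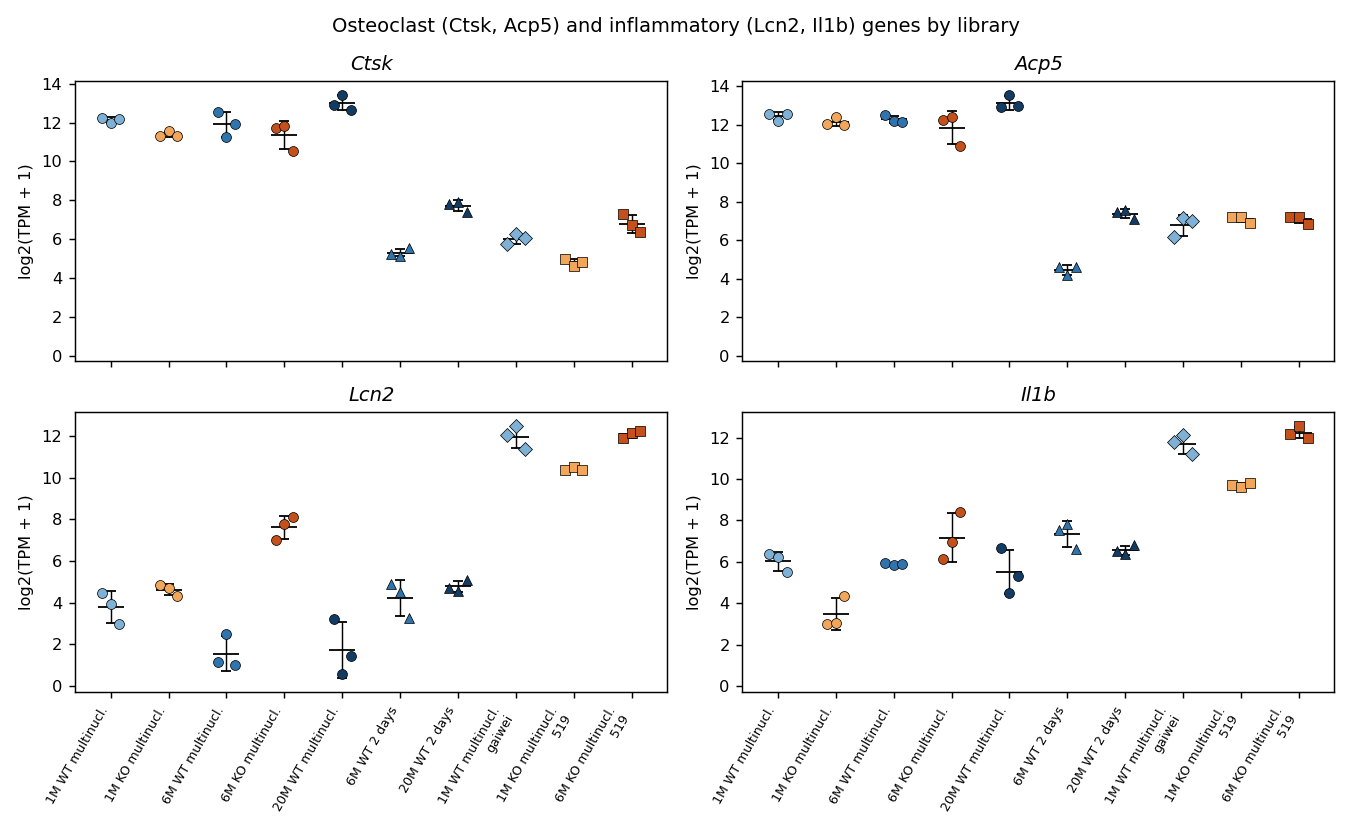
Log2(TPM + 1) of the osteoclast genes Ctsk and Acp5 and the inflammatory genes Lcn2 and Il1b in each library.

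Some libraries without a set mark stood apart from their group. In 6-month WT replicate 2, the mitochondrial gene mt-Co1 was at 2389 TPM, against 22530 and 20010 in the 2 other libraries of its group, and mitochondrial genes held 3.43% of TPM against 9.74% and 9.0%. Nnt was at 12.5 TPM there against 29.1 and 27.8. By correlation 1-month WT replicate 1 was nearest to 6-month WT replicate 4 and not to its own group, and it lay at -4.9 on the first principal component, against 38.9 and 45.6. In 6-month Terc-/- replicate 4 Ctsk was at 1499 TPM against 3392 and 3576. All were kept. Counts without 6-month WT replicate 2 are given with each comparison it enters, and those without other libraries where they moved by more than 1.5 times.

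At 1 month, Ctsd, Folr2 and Igf1 were higher in Terc-/- than in WT cells, and Cd74, Crabp2 and Col1a1 were lower. Ctsd, the lysosomal protease cathepsin D, was at 14730 ± 698 TPM in Terc-/- and 7093 ± 643 in WT (log2 fold change 1.16, SE 0.10), and Folr2, a folate receptor of tissue macrophages, at 83.5 ± 25.2 and 16.5 ± 3.96 (2.52, SE 0.25). Igf1, a growth factor that osteoclasts release to bone-forming cells, was at 347 ± 24.0 and 84.5 ± 13.6 (2.14, SE 0.23). Cd74 (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652), the chaperone of MHC class II, fell to 42.8 ± 23.2 from 290 ± 37.9 TPM (-2.79, SE 0.34). Crabp2, which carries retinoic acid, fell to 2.09 ± 0.604 from 247 ± 125 (-6.06, SE 0.36), and Col1a1, the main collagen of bone matrix, to 51.3 ± 20.6 from 515 ± 257 (-3.32, SE 0.35). Pmaip1, a p53 target that promotes cell death, was at 13.8 ± 3.36 and 64.3 ± 22.1 (-2.17, SE 0.22).

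In this comparison 3974 of 14238 genes were called (1774 higher, 2200 lower), 121 of them on the X and 5 on the Y chromosome. After median-ratio scaling 2318 were higher and 2202 lower, so the larger number of lower genes depended on scaling. For Ctsd the limma test with Benjamini-Hochberg adjustment gave adjusted p = 3.7e-08, for Cd74 1.5e-06, each with the 3 libraries of 1 genotype beyond the 3 of the other. Between the 519 (Terc-/-) and gaiwei (WT) libraries alone, where genotype and library set were fully confounded, 306 genes were called, and Cd74 (-0.58), Col1a1 (-0.68), Crabp2 (-0.64) and Pmaip1 (-0.59) were not among them.

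Lysosomal genes were higher in Terc-/- at 1 month for 12 of 25 and lower for none, the same adjusted over the list alone (median 0.30, camera adjusted p = 8.1e-05, adjusted p = 0.66 with an estimated correlation). MHC class II and dendritic cell genes were lower for 8 of 13 and higher for 1, the same adjusted over the list alone (median -0.70, camera adjusted p = 0.0019, adjusted p = 0.66 with an estimated correlation). Cholesterol synthesis genes were lower for 10 of 20, or 12 adjusted over the list alone (median -0.65, camera adjusted p = 0.0011, adjusted p = 0.66 with an estimated correlation), among them Fdps at 64.1 ± 3.65 against 123.4 ± 6.86 TPM (-1.06, SE 0.12). The osteoclast (4 higher, 2 lower), p53 target (3 higher, 8 lower), senescence (1 higher, 5 lower) and cell cycle lists (4 higher, 1 lower) were not called by camera.

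At 6 months, Lcn2, Nos2 and Il6 were higher in Terc-/- than in WT cells, and H2-Eb1 and Pmaip1 were lower. Lcn2 (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252), an iron-binding protein of innate immunity, was at 205 ± 72.7 TPM in Terc-/- and 2.29 ± 2.06 in WT (log2 fold change 5.74, SE 0.50). Nos2, the inducible nitric oxide synthase, was at 56.3 ± 36.3 and 3.95 ± 3.15 (3.86, SE 0.44), and Il6 (ENSMUSG00000025746, chromosome 5, 30013114 to 30019981), a cytokine that promotes bone loss, at 29.96 ± 11.9 and 6.40 ± 0.975 (2.08, SE 0.29). Id2, which restrains osteoclast formation, was at 239 ± 13.2 and 84.5 ± 22.1 (1.56, SE 0.15), and the matrix proteoglycan Dcn at 80.8 ± 16.6 and 1.74 ± 0.744 (4.88, SE 0.40). H2-Eb1, an MHC class II chain, fell to 17.2 ± 12.2 from 106 ± 8.97 (-3.09, SE 0.43), and Pmaip1 to 14.4 ± 4.75 from 63.3 ± 15.1 (-2.02, SE 0.22).

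Of 4117 called genes 2624 were higher and 1493 lower, with a median over all genes of 0.15. After median-ratio scaling the median was 0.01 and 51.7% of calls were higher, against 63.7% as deposited. Without 6-month WT replicate 1 the count was 6461, and without replicate 2 it was 3788 (1753 higher, 2035 lower). The limma test gave a Benjamini-Hochberg adjusted p = 1.2e-08 for Lcn2 (log2 fold change 5.74) and 5e-08 for Id2 (1.56), each with 3 of 3 Terc-/- libraries above the 3 WT libraries. With only libraries without a set mark 2564 genes were called, and with only these 2 groups in the fit 640, where Rpl5 (-0.46) was not among them.

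Inflammatory genes were higher in Terc-/- at 6 months for 17 of 27 and lower for 1, or 17 and 2 adjusted over the list alone (median 0.98, camera adjusted p = 6.3e-05, adjusted p = 0.35 with an estimated correlation). Of the 3 Terc-/- libraries without a set mark, replicate 4 had the highest inflammatory mean (6.55 against 5.64 and 5.88) and the lowest osteoclast mean (5.76 against 6.74 and 6.73), a shift in the direction of the 519 libraries. Without it Lcn2 (5.47), Nos2 (3.64) and Il6 (1.91) were still called. Neutrophil markers were higher for 5 of 6, the same adjusted over the list alone (median 1.64, camera adjusted p = 0.0011, adjusted p = 0.16 with an estimated correlation). The neutrophil gene S100a9, however, was at 0 TPM in these libraries of both genotypes without a set mark, so the list did not show that neutrophils were present. NF-kB pathway genes were higher for 16 of 21, or 19 adjusted over the list alone (median 0.76, camera adjusted p = 1.1e-06, adjusted p = 0.35 with an estimated correlation). Ribosomal protein genes were lower for 24 of 38, or 27 adjusted over the list alone (median -0.44, camera adjusted p = 9.4e-14, adjusted p = 0.35 with an estimated correlation), with Rpl5 at 747 ± 7.28 against 1025 ± 20.3 TPM (-0.53, SE 0.07). The osteoclast (5 higher, none lower), p53 target (6 higher, 1 lower), senescence (9 higher, 2 lower) and cell cycle lists (2 higher, 2 lower) were not called. After median-ratio scaling the cell cycle list held 1 higher and 8 lower genes, and hypoxia targets turned from 4 higher and 2 lower to 3 and 4. In libraries without a set mark alone, 740 genes were higher in Terc-/- at both ages against 144.8 expected of independent calls, and 482 were lower against 95.09. No library was shared between the ages, but genes are correlated, so independent calls do not measure chance. Outside X and Y, 89.9% of genes called at 1 month kept their sign at 6 months. Another split of the 6-month libraries, not by genotype, reached 85.6%. Sex and genotype were also confounded at 1 month.

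Il6, Cxcl3 and Nqo1 had a more positive difference between Terc-/- and WT at 6 months than at 1 month. Il6 was at 1.31 ± 0.0875 TPM in 1-month and 29.96 ± 11.9 in 6-month Terc-/- cells, and at 8.94 ± 1.81 and 6.40 ± 0.975 in WT (log2 ratio of the fold changes 4.24, SE 0.38). Cxcl3, a neutrophil-attracting chemokine, went from 22.8 ± 10.8 to 271 ± 182 in Terc-/- and from 99.6 ± 52.98 to 33.9 ± 9.58 in WT (4.28, SE 0.63). The antioxidant enzyme gene Nqo1 stayed at 28.5 ± 5.00 and 28.4 ± 5.77 in Terc-/- and went from 42.1 ± 6.00 to 8.55 ± 0.864 in WT (2.11, SE 0.22). This contrast called 1318 genes (921 higher, 397 lower), a count that other splits of the libraries also reached, and Il6 had a limma Benjamini-Hochberg adjusted p = 4.8e-08 (4.24, 3 of 3 6-month Terc-/- libraries without a set mark above the 1-month ones). The median over all genes was 0.22 and 69.9% of calls were higher, against 0.01 and 59.4% after median-ratio scaling. The count was 3734 without 1-month WT replicate 1, 488 without replicate 3, 556 without replicate 4, 870 without 1-month Terc-/- replicate 519_2, and 5378, 770 (496 higher, 274 lower) and 2114 without 6-month WT replicates 1, 2 and 4. With only libraries without a set mark it was 182. Because the 1-month WT cells read as female, sex enters this contrast.

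Inflammatory genes had a more positive Terc-/- effect at 6 months for 14 of 27, or 19 adjusted over the list alone (median 1.31, camera adjusted p = 2.8e-08, adjusted p = 0.19 with an estimated correlation). Senescence markers did so for 9 of 18, or 10 adjusted over the list alone (median 0.88, camera adjusted p = 0.00013, adjusted p = 0.19 with an estimated correlation). Lysosomal genes turned from 2 higher to 4 lower under median-ratio scaling.

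Within Terc-/- cells, Il6, Il1a and Csf3 rose between 1 and 6 months. Il6 rose by 3.83 (SE 0.22), Il1a by 3.42 (SE 0.37; 67.8 ± 44.6 against 4.06 ± 3.02 TPM) and Csf3, the growth factor of neutrophils, by 3.12 (SE 0.29; 13.8 ± 9.85 against 0.573 ± 0.237). Lpl, which releases fatty acids from lipoproteins, fell by 1.71 (SE 0.20; 84.4 ± 48.8 against 294 ± 32.3), and Ctsh, a lysosomal protease, by 0.87 (SE 0.10; 155 ± 13.1 against 231 ± 13.7). These estimates also rest on the 519 libraries. In all 1561 genes were called (1076 higher, 485 lower), with a limma Benjamini-Hochberg adjusted p = 5.7e-12 for Il6 (3.83, 3 of 3 older libraries without a set mark above the younger). With each library set of a group as its own group 456 genes were called, and with only libraries without a set mark 258. Inflammatory genes rose for 19 of 27, or 21 adjusted over the list alone (median 1.49, camera adjusted p = 3.9e-20, adjusted p = 0.026 with an estimated correlation).

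In WT cells, Cck was lower and Ccl12 was higher at 6 months than at 1 month. Cck, a peptide hormone of gut and nerve cells, fell to 0.224 ± 0.2675 from 34.4 ± 14.35 TPM (log2 fold change -4.79, SE 0.41), and Ctsl, the lysosomal protease cathepsin L, to 1261 ± 199 from 2325 ± 93.7 (-0.89, SE 0.13). Ccl12, a monocyte-attracting chemokine, rose to 58.9 ± 18.5 from 11.9 ± 3.52 (2.19, SE 0.37). Cdkn2a, a cell cycle inhibitor that marks senescence, was at 81.9 ± 25.8 against 159 ± 34.9 (-0.97, SE 0.20). Msmo1, an enzyme of cholesterol synthesis, was at 50.1 ± 6.40 against 91.7 ± 9.16 (-0.86, SE 0.15). In this contrast sex and age were confounded.

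Of 788 called genes 289 were higher and 499 lower, with a limma Benjamini-Hochberg adjusted p = 3e-08 for Cck (-4.79, 3 of 3 older libraries below the younger). The median over all genes was -0.14, and 0.01 after median-ratio scaling. The count was 1719, 332 and 355 without 1-month WT replicates 1, 3 and 4, and 4446 and 1196 without 6-month replicates 1 and 4. Without 6-month replicate 2 it was 529 (280 higher, 249 lower), so the larger number of lower genes rested on this library. With only libraries without a set mark it was 482. With only the 2 groups in the fit it was 86, and Ctsl (-0.89), Cdkn2a (-0.97) and Msmo1 (-0.86) were not among them. After median-ratio scaling Cdkn2a (-0.78) was not called either. With no set term, where the gaiwei libraries enter the 1-month mean, Ccl12 (0.56) and Cdkn2a (-0.13) were not called. Interferon response genes were lower for 9 of 32, or 20 adjusted over the list alone (median -0.82, camera adjusted p = 4.6e-06, adjusted p = 0.61 with an estimated correlation).

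In multinucleated WT cells, Hspa5, Ero1l and Ndrg1 were higher at 20 than at 6 months, and Birc5 and Ccl2 were lower. Hspa5 (ENSMUSG00000026864, chromosome 2, 34771970 to 34777547), the main chaperone of the endoplasmic reticulum, was at 2268 ± 194 TPM against 566 ± 112 (log2 fold change 2.02, SE 0.14), and Ero1l, which forms disulfide bonds there, at 266 ± 63.7 against 50.5 ± 18.4 (2.42, SE 0.26). Ndrg1, a target of hypoxia, was at 43.0 ± 13.9 against 5.43 ± 1.61 (2.75, SE 0.27). Oscar, an osteoclast receptor for collagen, was at 136 ± 34.7 against 44.0 ± 19.05 (1.66, SE 0.32). Birc5 (ENSMUSG00000017716, chromosome 11, 117849251 to 117855743), needed for cell division, fell to 9.53 ± 1.30 from 50.4 ± 8.94 (-2.28, SE 0.23), and Ccl2, which attracts monocytes, to 24.7 ± 11.4 from 124 ± 16.5 (-2.37, SE 0.27).

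Of 3475 called genes 2494 were higher and 981 lower, with a limma Benjamini-Hochberg adjusted p = 2.3e-10 for Hspa5 (2.02, 3 of 3 older libraries above the younger) and 2.5e-07 for Birc5 (-2.28, 3 of 3 below). The median over all genes was 0.25 and 71.8% of calls were higher, against 0.01 and 46.8% after median-ratio scaling. The count was 1979, 2023 and 1971 without 20-month replicates 1, 3 and 4, and 7368 and 1745 (860 higher, 885 lower) without 6-month replicates 1 and 2. With only libraries without a set mark 2173 genes were called, and with only these 2 groups in the fit 160 were called, and Oscar was not among them.

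Unfolded protein response genes were higher at 20 than at 6 months for 22 of 23, the same adjusted over the list alone (median 1.57, camera adjusted p = 1.8e-21, adjusted p = 0.0056 with an estimated correlation). Hypoxia targets were higher for 14 of 16, or 15 adjusted over the list alone, and for 10 after median-ratio scaling (median 1.34, camera adjusted p = 9.7e-11, adjusted p = 0.078 with an estimated correlation). Cell cycle genes were lower for 27 of 34, or 31 adjusted over the list alone (median -1.31, camera adjusted p = 4.5e-30, adjusted p = 0.078 with an estimated correlation). Osteoclast genes were higher for 14 of 34, or 19 adjusted over the list alone, and for 7 after median-ratio scaling (median 0.77, camera adjusted p = 0.0034, adjusted p = 0.87 with an estimated correlation). Stromal markers were higher for 6 of 17 and lower for 1, the same adjusted over the list alone, and the list was not called (median 0.42, camera adjusted p = 0.32), with Col1a1 at 1490 ± 156 against 335 ± 65.3 TPM (2.16, SE 0.38). Macrophage markers turned from 4 higher and 3 lower to 1 higher and 4 lower under that scaling, and negative regulators of osteoclast formation from 6 and 3 to 5 and 6.

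The same 20-month libraries were also compared with 1-month WT cells, where H19 and Adm were higher and Nqo1 and Rrm2 lower. H19, an imprinted RNA of fetal growth, was at 56.5 ± 6.32 TPM against 0.647 ± 0.0922 (log2 fold change 5.12, SE 0.29), and Hspa5 at 2268 ± 194 against 729.5 ± 114 (1.64, SE 0.14). Adm, a hypoxia target that widens vessels, was at 32.5 ± 7.43 against 2.40 ± 1.51 (3.40, SE 0.37). Nqo1 fell to 4.47 ± 1.01 from 42.1 ± 6.00 (-2.98, SE 0.18), and Rrm2, which supplies DNA building blocks, to 10.1 ± 1.505 from 42.6 ± 1.90 (-1.98, SE 0.19). Cdkn2a was at 75.7 ± 11.7 against 159 ± 34.9 (-1.05, SE 0.20), but was not called with no set term (-0.21), where the gaiwei libraries enter the 1-month mean. Sex and age were confounded here too.

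Of 2453 called genes 1374 were higher and 1079 lower, and 1588 were called without 1-month WT replicate 1 (735 higher, 853 lower). The limma Benjamini-Hochberg adjusted p was 1.5e-11 for Nqo1 (-2.98, 3 of 3 older libraries below the younger). Median-ratio scaling left 46.1% of calls higher. Antioxidant genes were lower for 15 of 24, or 18 adjusted over the list alone (median -0.65, camera adjusted p = 6.9e-14, adjusted p = 0.022 with an estimated correlation). Senescence markers were lower for 7 of 18, or 8 with 1 higher adjusted over the list alone (median -0.63, camera adjusted p = 2e-04, adjusted p = 0.18 with an estimated correlation).

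**Figure D3:**
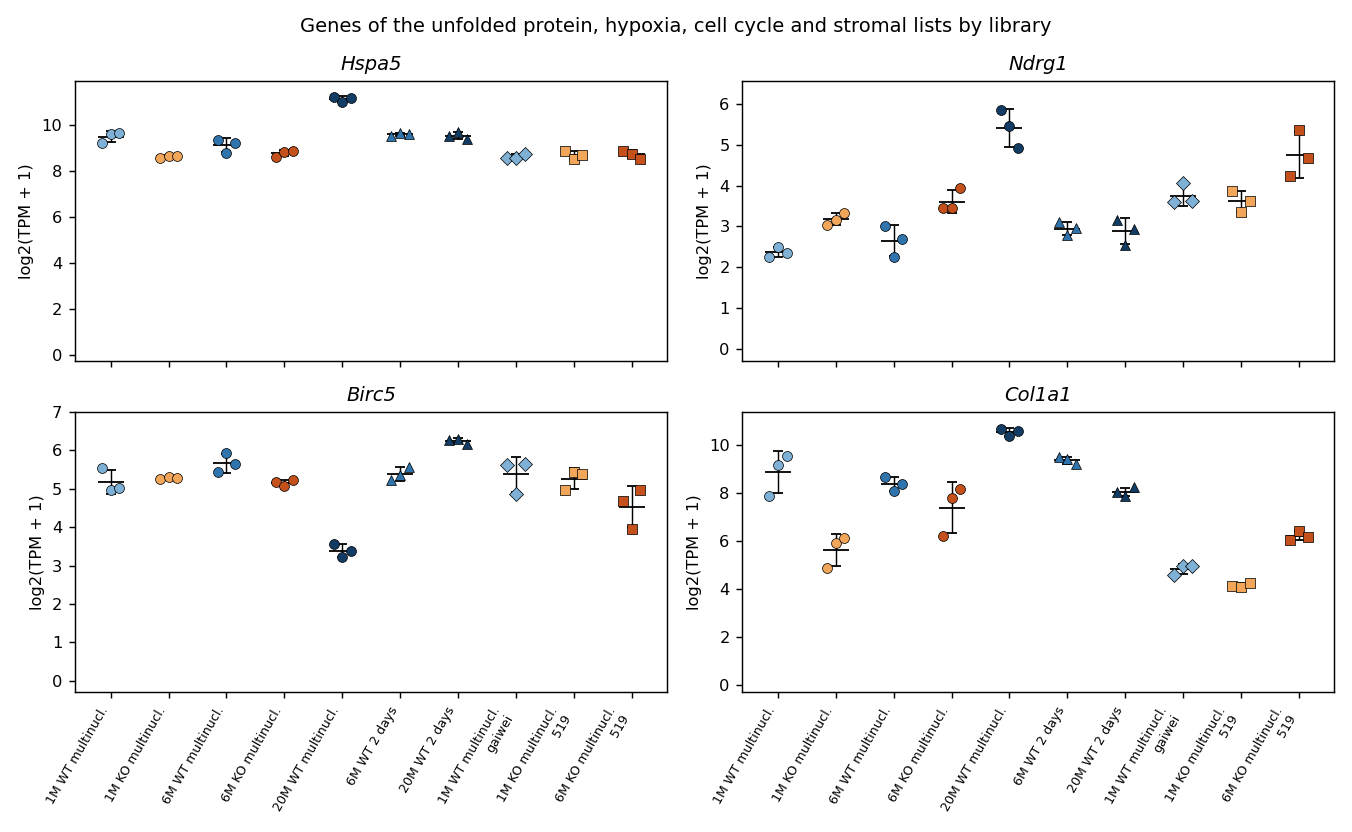
TPM of genes that differed with age in multinucleated cells, by library and group.

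At 2 days of culture, Acp5 and Dcstamp were higher in cells of 20-month than of 6-month WT mice. Acp5 was at 165 ± 25.5 TPM against 21.2 ± 3.68 (log2 fold change 2.91, SE 0.29), and Dcstamp, needed for cell fusion, at 6.65 ± 2.93 against 0.423 ± 0.494 (2.40, SE 0.39). Igkc, an immunoglobulin light chain of B cells, was at 80.8 ± 14.5 against 2.98 ± 2.49 (4.52, SE 0.29), and S100a9, a neutrophil protein, at 32.5 ± 23.9 against 0.132 ± 0.229 (4.69, SE 0.35). Cdkn2a fell to 11.9 ± 2.78 from 30.9 ± 6.57 (-1.31, SE 0.20), and Lmod1, an actin-binding protein of smooth muscle, to 7.52 ± 1.52 from 41.1 ± 6.02 (-2.31, SE 0.24).

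Of 1791 called genes 838 were higher and 953 lower, with a limma Benjamini-Hochberg adjusted p = 1.7e-07 for Acp5 (2.91, 3 of 3 older libraries above the younger). The count was 980 without 20-month 2-day replicate 3, and 1077 and 1030 without 6-month 2-day replicates 1 and 2. Osteoclast genes were higher for 11 of 34, or 12 with 1 lower adjusted over the list alone (median 0.32, camera adjusted p = 7.9e-05, adjusted p = 0.6 with an estimated correlation), and cell cycle genes for 9 of 34, or 13 adjusted over the list alone (median 0.51, camera adjusted p = 2e-07, adjusted p = 0.54 with an estimated correlation). Stromal markers were lower for 5 of 17 and higher for 1, or 8 and 1 adjusted over the list alone (median -0.55, camera adjusted p = 0.016, adjusted p = 0.58 with an estimated correlation). Histone genes were lower for 8 of 14, or 9 adjusted over the list alone (median -0.80, camera adjusted p = 3.4e-07, adjusted p = 0.00027 with an estimated correlation). The p53 targets were lower for 8 of 24 and higher for 1, the same adjusted over the list alone (median -0.27, camera adjusted p = 0.0017, adjusted p = 0.54 with an estimated correlation). Podosome genes turned from 3 higher and 2 lower to 4 and 6 under median-ratio scaling.

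From 2 days to multinucleated cells, Acp5 rose in WT cells of both ages. At 6 months Acp5 rose to 4967 ± 620 TPM from 21.2 ± 3.68 (log2 fold change 7.81, SE 0.29) and Ctsk to 4118 ± 1816 from 38.8 ± 5.55 (6.61, SE 0.41). Cd74 rose to 401 ± 106 from 2.32 ± 0.120 (6.89, SE 0.36), while Il11, a cytokine of stromal cells, fell to 1.79 ± 1.04 from 47.5 ± 8.07 (-4.19, SE 0.35). At 20 months Acp5 rose to 9196 ± 2482 from 165 ± 25.5 (5.77, SE 0.29), Hspa5 to 2268 ± 194 from 746 ± 80.3 (1.60, SE 0.14), and Rrm2 fell to 10.1 ± 1.505 from 124 ± 8.99 (-3.50, SE 0.19).

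At 6 months 7240 genes were called (1692 higher, 5548 lower), and at 20 months 4447 (1843 higher, 2604 lower). The limma Benjamini-Hochberg adjusted p of Acp5 was 7.7e-16 at 6 months (7.81) and 2.6e-13 at 20 months (5.77), with 3 of 3 multinucleated libraries above the 2-day libraries at each age. At 6 months the median over all genes was -0.33 and 23.4% of calls were higher, against -0.02 and 47.0% after median-ratio scaling, and without replicate 2 the count was 5309 (1840 higher, 3469 lower). At 20 months 41.4% were higher as deposited and 50.9% after that scaling (2367 higher, 2285 lower).

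Osteoclast genes were higher in multinucleated cells for 26 of 34 and lower for 2 at 6 months, the same adjusted over the list alone (median 1.58, camera adjusted p = 9.1e-26, adjusted p = 0.1 with an estimated correlation). At 20 months they were higher for 31, or 32 adjusted over the list alone (median 2.30, camera adjusted p = 1.6e-28, adjusted p = 0.084 with an estimated correlation). The p53 targets were lower for 16 of 24 at 6 months, or 17 adjusted over the list alone (median -0.83, camera adjusted p = 0.042, adjusted p = 0.96 with an estimated correlation). Under median-ratio scaling 5 lists turned at 6 months: macrophage markers from 2 higher and 6 lower to 7 and 4, NF-kB genes from 4 and 5 to 10 and 2, glycolysis genes from 1 and 11 to 4 and 2, negative regulators of osteoclast formation from 1 and 7 to 7 and 2, and telomere genes from 3 and 5 to 5 and 1. At 20 months p53 targets went from 1 higher and 2 lower to 4 and 1.

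The change from 2 days to multinucleated cells itself differed between the ages. Hspa5 went from 781 ± 39.2 to 566 ± 112 TPM at 6 months and from 746 ± 80.3 to 2268 ± 194 at 20 months (log2 ratio of the fold changes 2.09, SE 0.19). Birc5 went from 41.0 ± 5.30 to 50.4 ± 8.94 at 6 months and from 75.5 ± 3.75 to 9.53 ± 1.30 at 20 months (-3.15, SE 0.33). Col1a1 went from 656 ± 64.7 to 335 ± 65.3 and from 262 ± 33.7 to 1490 ± 156 (3.49, SE 0.53). In all 2881 genes were called (1887 higher, 994 lower), with a limma Benjamini-Hochberg adjusted p = 5.6e-08 for Hspa5 (2.09, 3 of 3 multinucleated libraries above the 2-day ones at 20 months). The median over all genes was 0.24 and 65.5% of calls were higher, against 0.01 and 52.3% after median-ratio scaling, and 5366 genes were called without 6-month multinucleated replicate 1. Without replicate 2 of that group 2830 were called (1475 higher, 1355 lower). Of 100 splits of the libraries, 10 reached the count of 2881 with main effects left in, and 1, the real one, with them removed.

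Unfolded protein response genes had a more positive change at 20 months for 19 of 23, or 20 adjusted over the list alone (median 1.78, camera adjusted p = 5.1e-16, adjusted p = 0.047 with an estimated correlation). Cell cycle genes had a more negative one for 30 of 34, or 31 adjusted over the list alone (median -1.92, camera adjusted p = 9e-29, adjusted p = 0.096 with an estimated correlation). The osteoclast list (4 higher, 6 lower) was not called, and its median of 0.44 and mean of 0.09 lay opposite to the downward test.

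**Figure D4:**
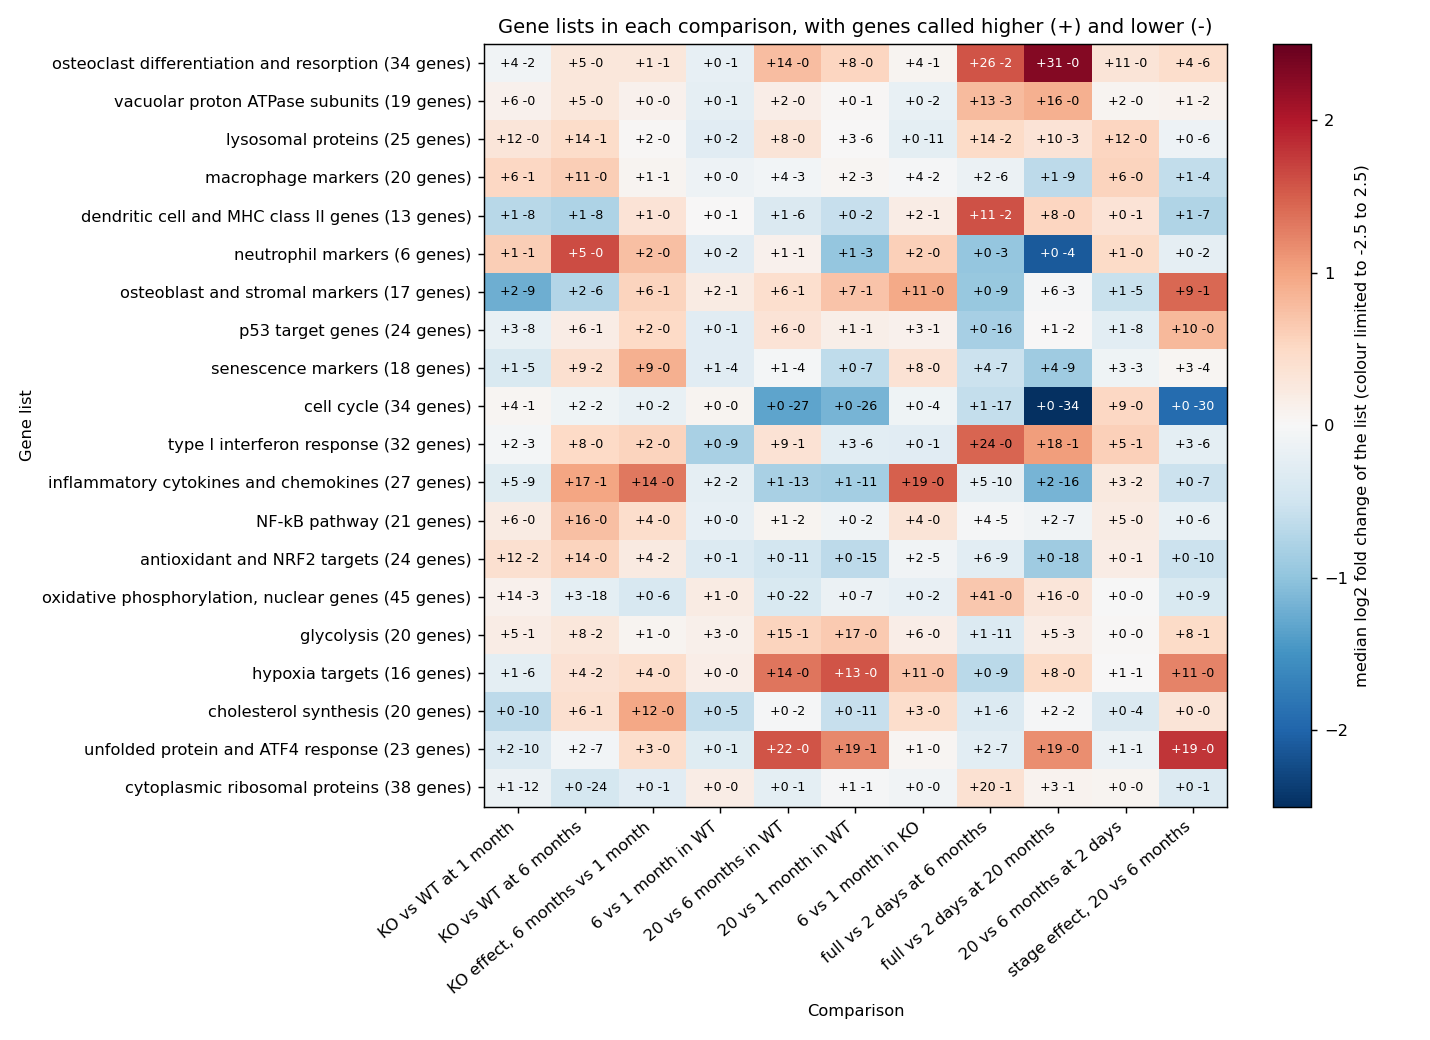
Median log2 fold change of gene lists in each comparison.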

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

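Among the tests in this part, the other splits of the libraries, the sex and stromal tests and the comparison of the libraries with a set mark with the 2-day cultures were chosen after the results were seen, and only the scaling test was written before. The splits with main effects removed were chosen after those with them left in had been seen.

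In 189 groups of 6 values, 12 held a library far from the other 5, and chance finds about 1 in 20, or 9.45. In 1-month Terc-/- cells replicate 4 was high in Eif2s3y (19.2 TPM, nearest 14.4), Fn1 (495, nearest 238) and H2-Aa (12.9, nearest 4.3), and replicate 519_1 had a relative depth of 1.44 (nearest 1.16). In 1-month WT cells replicate 4 was high in Terc (1.13, the others at 0) and Ndufa4l2 (2.45, nearest 0.133), and replicate gaiwei2 was low in Gas6 (14.9, nearest 32.2). In 6-month Terc-/- cells replicate 2 was high in Cd74 (183, nearest 72) and H2-Eb1 (31.4, nearest 10.2), replicate 4 in Cck (15.6, nearest 6), replicate 519_3 in Dcn (220, nearest 98.2), and replicate 519_2 had a relative depth of 1.34 (nearest 1.01). These groups mix libraries with and without a set mark, so a chance rate meant for 6 values of a single population may not apply to them. Groups with only 3 libraries, the multinucleated 6-month WT group among them, were not screened.

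The effect of Terc-/- differed between 6 months and 1 month by the limma interaction test for 1318 genes, among them Il6 (4.24), Ptgs2 (3.57), Cxcl3 (4.28), Lcn2 (4.57), Stfa3 (4.63), Cck (5.66), Mfap5 (4.50), Cyp51 (1.44), Mmp13 (3.0), Col1a1 (2.39), Nqo1 (2.11), F13a1 (-2.79), Apoe (-1.80) and Hpgd (-2.88). With only libraries without a set mark 182 genes were called, and Cyp51 (0.91), Col1a1 (2.24), F13a1 (-1.91), Apoe (-0.96) and Hpgd (-2.05) were not among them. Chance was not excluded: 20 of 100 splits gave as many genes, the highest other 7051, and 23 of 100 with main effects left in, the highest other 5665. A split calling several times the real count points to a structure of the samples, and the highest splits exchanged replicate 1 of both 1-month and 6-month WT cells, among others. The count was 3734, 488 and 556 without 1-month WT replicates 1, 3 and 4, 870 without 1-month Terc-/- replicate 519_2, and 5378, 770 and 2114 without 6-month WT replicates 1, 2 and 4.

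The change from 2 days to multinucleated cells differed between 20 and 6 months for 2881 genes, among them Itga11 (5.07), Thbs2 (4.57), Adamts4 (4.13), Hspa5 (2.09), Pdia6 (1.78), P4ha2 (2.65), Adm (3.05), Col1a1 (3.49), Cdkn2a (1.23), Tnfrsf10b (1.91), Birc5 (-3.15), Rrm2 (-2.03), Acp5 (-2.04), Dcstamp (-2.45), Cd74 (-2.95) and Tnf (-2.45). Of 100 splits with main effects removed 1, the real one, gave as many genes, and the highest other gave 888. With main effects left in 10 of 100 did, the highest other giving 4362. Without 6-month multinucleated replicate 1 the count was 5366. After median-ratio scaling Cdkn2a (0.94) was not called. With no set term 814 genes were called, and Adm, Acp5, Dcstamp, Cd74, Tnf, Col1a1, Cdkn2a and Tnfrsf10b were not among them. Their fold changes were the same as above, since these groups hold no library with a set mark. Only the spread, which was estimated from all libraries, took in the set differences of other groups.

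Other splits were counted for the remaining comparisons as well. For 6 against 1 month in Terc-/- only the real split of 100 gave 1561 genes or more (highest other 969). For the 519 term only the real split of 100 gave 7187 (highest other 4255), so the share was under 0.05 for these 2. The splits exchanged single libraries, and the labels do not say whether these came from separate animals. Chance differences between animals or cultures were therefore not excluded. With 3 libraries against 3 there are 10 splits, and a share under 0.05 cannot be reached. There the real split and the highest other gave 3974 and 2479 genes for Terc-/- against WT at 1 month (1 of 10 as large), 4117 and 5088 at 6 months (2 of 10), 788 and 6800 for 6 against 1 month in WT (3 of 10), 3475 and 47 for 20 against 6 months (1 of 10), 2453 and 1 for 20 against 1 month (1 of 10), 1791 and 4 at 2 days (1 of 10), 7240 and 14 for the stages at 6 months (1 of 10), 4447 and 3 at 20 months (1 of 10), and 7742 and 5 for the gaiwei term (1 of 10). The highest split exchanged 1-month WT replicate 1 for Terc-/- against WT at 1 month, 6-month WT replicate 1 at 6 months and both for 6 against 1 month in WT, a structure of these samples.

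The libraries with a set mark had low osteoclast and high inflammatory RNA. Cells at the stage of the 2-day cultures may account for the osteoclast genes: in 9 of 9 libraries the list's mean lay at or below the highest 2-day library. Other lists differed from the 2-day cultures. The cell cycle mean was 3.62 to 4.27 in the 519 and 3.64 to 4.59 in the gaiwei libraries, against 5.04 to 5.71 at 2 days. The stromal mean was 2.78 to 3.99 and 3.24 to 3.32, against 4.86 to 5.65. The mean of the inflammatory genes lay above the highest 2-day library by more than the SD of the 2-day libraries in 9 of 9. Their level was thus not that of these 2-day cultures. The 2-day cultures were all of WT mice and had no set mark. None shared both genotype and age with a library with a set mark. An early stage therefore cannot be excluded for the inflammatory genes. Scaling by a few abundant genes is excluded as the whole cause, since after median-ratio scaling the higher of the 2 medians of the osteoclast list was still -1.69. Batch, culture and handling stay open, as the meaning of the marks is not given in the sources used here.

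The calls between Terc-/- and WT at 1 month could be due to sex, since only the 1-month WT libraries without a set mark expressed Xist. Outside X and Y, 73.4% of the genes called in libraries without a set mark had the same sign between the 519 and gaiwei libraries, where no library expressed Xist, but another of the 10 splits reached 72.2%. At 6 months 89.9% had the same sign, and another split reached 85.6%. The shares did not exceed those of other splits by the 10 points asked for, so sex, genotype and a structure of the samples cannot be told apart for these genes.

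A smaller share of stromal cells in Terc-/- cultures may underlie the lower RNA of stromal markers. Of the abundant stromal markers 7 of 8 were called lower at 1 month and 5 of 9 at 6 months in libraries without a set mark. Col1a1 and Col1a2 were not called lower at 6 months. Dcn was higher instead at both ages (1.51 and 4.91). A smaller share of stromal cells and a change in gene activity cannot be told apart, because most but not all markers were lower.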

How the results depend on the processing

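The pseudocount of 0.1, median-ratio scaling, stricter filter, removal of mitochondrial genes, separate set groups and comparison within libraries with a set mark were chosen after the results were seen. Of 250 counts of genes under alternatives 195 stayed within 1.5 times and 55 moved, of 263 counts of lists 246 stayed and 17 moved, and of 4587 values of named genes 4380 kept call and direction, 196 lost the call and 11 reversed. No count of genes moved that far with no filter, the pseudocount of 0.1, median-ratio scaling or without mitochondrial genes. Estimated correlation: lists called fell to 0 for Terc-/- against WT at 1 month, at 6 months and in the interaction, 1 for 6 against 1 month in WT, 2 for 20 against 6 and 3 for 20 against 1 month, 1 for 6 against 1 month in Terc-/-, 0 and 1 for the stages at 6 and 20 months, 2 at 2 days, 1 for the stage interaction, and 4 and 3 for the 519 and gaiwei terms. No filter: lists 21 for Terc-/- at 6 months, 17 for the interaction, 19 for 6 against 1 month in WT. No set term: genes 488 and 2680 for Terc-/- at 1 and 6 months, 457 for the interaction, 821 for 20 against 6 months, 356 for 6 against 1 month in Terc-/-, 4227 and 2086 for the stages at 6 and 20 months, 438 at 2 days and 814 for the stage interaction, with Siglec15 at -0.24 (Terc-/- at 6 months) and Isg15 0.09, Oas3 0.12 and Ccl2 -1.21 (6 against 1 month in WT). These named genes had the opposite sign in the main fit. Without the term, set differences entered the Terc-/- and 1-month WT means. The groups of 20 against 6 months, the stages, 2 days and the stage interaction hold no library with a set mark, and their fold changes stayed the same. Acp5 at 2 days was at 2.91 with and without the term, but was not called without it. Each gene's spread was estimated from all 30 libraries, so set differences left in that spread lowered these counts. Only libraries without a set mark: 2564 (Terc-/- at 6 months), 182 (interaction), 482 (6 against 1 month in WT), 2173 (20 against 6) and 258 (Terc-/- ages), Ctsk -0.03 in the last, where the main fit called it higher. With no filter Ctsk was at 0.98 in that comparison and was not called. Only the groups compared: 640 for Terc-/- at 6 months, 502 for the interaction, 86 for 6 against 1 month in WT, 160 for 20 against 6 months, 2405 for the Terc-/- ages, 1828 and 7198 for the stages at 6 and 20 months, 4824 at 2 days and 1720 for the stage interaction. Each set its own group: interaction 412, Terc-/- ages 456, Ctsk again -0.03. Libraries with a set mark alone, Terc-/- at 1 month: 306, Hspa5 0.06, Pdia6 0.04, Xist 0.00 and Ddx3y -0.22, the last 2 because these libraries are all male by Xist, and Eif2s3y -1.88. Hspa5, Pdia6, Ddx3y and Eif2s3y had the opposite sign in the main fit. Stricter filter, with fewer genes tested: 1582 (20 against 1), 1117 (2 days), 1911 (stage interaction). With a replicate block the interaction gave 664, 6 against 1 month in WT 278 and 20 against 6 months 1480; replicate numbers did not pair the libraries, with r from -0.57 to 0.28 (median 0.02) and 9 of 49 above 0.1. Leaving out 1 library at a time, ranges were 3444 to 6461 for Terc-/- at 6 months (6461 without 6-month WT replicate 1), 488 to 5378 for the interaction (3734, 488 and 556 without 1-month WT replicates 1, 3 and 4, 870 without 1-month Terc-/- replicate 519_2, 5378, 770 and 2114 without 6-month WT replicates 1, 2 and 4), 332 to 4446 for 6 against 1 month in WT (1719, 332 and 355 without 1-month WT replicates 1, 3 and 4, 4446 and 1196 without 6-month replicates 1 and 4; lists 7 to 13, 7 without 6-month replicate 4), 1745 to 7368 for 20 against 6 months (1979, 2023 and 1971 without 20-month replicates 1, 3 and 4, 7368 and 1745 without 6-month replicates 1 and 2), 1588 to 2454 for 20 against 1 month (1588 without 1-month WT replicate 1), 980 to 1342 at 2 days (980 without 20-month replicate 3, 1077 and 1030 without 6-month replicates 1 and 2) and 2140 to 5366 for the stage interaction (5366 without 6-month multinucleated replicate 1); arms then hold 2 libraries. Where no cause is named, the cause was not tested. Alternatives of the plan that need counts (other size factors, library size alone, another count test, a filter on counts) were not run, as the unit is TPM. Depth is known only relative to the first library, so what it limits among genes with low values was not measured.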

Other observations

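Both ageing tests in this part were written before their results were seen, with their comparison with other splits added after, and the correlations between library sets were chosen after.

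Whether loss of Terc and ageing changed the same genes stayed open. Across 14238 genes, the fold changes of Terc-/- against WT at 6 months and of 20 against 1 month in WT, with no shared library, had r = -0.16, with 0.21 as the largest size among other splits. The bound written before, r below 0.1 against a shared direction, did not allow for sex: the 20-month libraries read as male and the 1-month WT libraries as female, so age and sex cannot be told apart in this pair. For Terc-/- against WT at 1 month and 20 against 6 months in WT r was -0.14, but other splits reached 0.44 in size, and sex enters the 1-month difference.

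The difference of the 519 libraries correlated across genes with that of the gaiwei libraries (r = 0.75), and with the change from 2 days to multinucleated cells at r = -0.33 (6 months) and -0.45 (20 months). For gaiwei the latter were -0.01 and -0.37. By correlation 28 of 30 libraries were nearest to one of their own group, and the others were 1-month WT replicate 1 and 6-month WT replicate 2.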
